A study of Mus musculus with 16 samples.

How the data were processed

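Total RNA from flow-sorted live CD4+CD8+ thymocytes of 16 mice was made into stranded RNA libraries (KAPA chemistry, RNA integrity number above 9, per the labels' protocols), with 1 library per mouse. The authors aligned the reads with Bowtie 1.0.0 and SAMtools 0.1.18 to GRCm38 (mm10), and listed edgeR 3.24.3, per the submitters' processing notes; the program that turned alignments into counts is not given in the sources used here. The deposited files hold, for each library, an estimated count (expected count) and a TPM value for each of 46517 gene identifiers. Of the deposited estimated counts above 0, 58.7% were whole numbers within 1e-6, so that the rest carried fractions from reads shared between transcripts or genes. The deposited TPM values summed to 1000000 in each library and were used in no test. Symbols, positions, biotypes, GC content and transcript lengths came from a GENCODE annotation of GRCm38, which gave a symbol for 46005 of the identifiers. The other 512 held 0.171% of the counts. No column was left unmapped to a sample.

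Estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1 for the list tests). Genes were kept by edgeR's filter on expression by group, library sizes were scaled by TMM, and a robust quasi-likelihood model with group and sex was fitted to all 16 libraries, which left 12 residual degrees of freedom. The p-values (two-sided) were adjusted by the Benjamini-Hochberg method over the 14933 genes tested, with a threshold of 0.05, and "adjusted p" of a gene means this edgeR value throughout. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are counts per 1000000 (CPM) on TMM-scaled library sizes, given as mean ± SD over mice. The common biological coefficient of variation was 0.128. Library totals lay between 17955743 and 35637813 estimated counts. Chi-square per degree of freedom between any 2 libraries of a group was 4.55 to 80.4, so no library was a re-run of another. Replicates are separate mice by their identifiers.

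The comparisons were knockout-labelled v control, transgenic v control, transgenic v knockout-labelled, male v female, and the difference of the transgenic effect between the sexes, fitted on control and transgenic libraries alone (14385 genes). Nfkbid levels were also compared by an exact two-sided permutation test of the difference of means. Gene lists (32) were tested with camera on voom-weighted values at a preset inter-gene correlation of 0.01, each against all other genes, with Benjamini-Hochberg adjustment over the 31 lists with at least 3 tested members. The lists covered the NF-kB and IkB family, NF-kB target genes, TCR-signal-induced genes, the BCL2 family, TCR signalling components, double-positive, mature single-positive and double-negative thymocyte genes, proliferation, type I interferon response, MHC class I presentation, glucocorticoid-induced, immediate-early and handling-stress, p53 target, unfolded protein and amino acid response, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded, ribosomal protein and nuclear oxidative phosphorylation genes, TCR alpha and beta variable segments, genes neighbouring Nfkbid, sex-check genes, and markers of B cells, macrophages and monocytes, dendritic cells, thymic epithelium, erythroid cells, granulocytes, stroma and endothelium, and NK, innate lymphoid and gamma-delta cells. For each list the members called higher or lower were counted after adjustment over all genes and again adjusted over the list alone.

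The groups, comparisons, tests, lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule took Nfkbid, the 7 largest changes in each direction among called genes with a mean of at least 1 CPM and an established symbol, and the 2 members with the smallest p of each list; in the sex comparisons it took the 5 genes with the smallest p. List members named outside this rule, and the gene families counted by symbol, were chosen after their values were seen. Results for some single genes are not reported here.

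Comparisons that share the controls were set against 20 simulations of unchanged groups sharing those controls, against the product of the numbers of calls, and against the 20 ways of giving each comparison 3 controls of its own. Alternative settings fixed beforehand were DESeq2 1.42.0, limma-voom, RLE size factors, library totals alone, no filter, a stricter filter (1 CPM in at least 5 libraries), a fit that is not robust, no sex term, only the groups compared, males only, the replicate number as a block, a test against a fold of 1.2, leaving out each of the 16 libraries, and for lists an estimated correlation or fry. Added after seeing the data were a correction for GC content and transcript length (a spline with 4 degrees of freedom per library, removed as an offset), the data without control replicate 2 and transgenic replicates 3 and 5 (high interferon-response transcripts), and the data without control replicate 1 and knockout replicates 1 to 3 (high MHC class II transcripts). The transgenic libraries, also high in class II transcripts, were kept in that last setting. For each comparison, 100 splits of the libraries into groups of the same sizes, the real one included, were fitted. Outlying libraries were sought by the gap of the highest or lowest value to its neighbour.

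The code was tested on simulated counts with the real libraries' means and sizes, in which 200 genes were changed. In knockout-labelled v control (14719 genes), 77% of genes changed 1.5-fold and 88% of those changed 2-fold were recovered. The shares were 71% and 90% for transgenic v control (14724 genes), 69% and 88% for transgenic v knockout-labelled (14700 genes), 83% and 96% for male v female (14708 genes), and 18% and 61% for the sex difference of the transgenic effect (14337 genes). With no change simulated, 0 genes and 0 lists were called in each of the 3 group comparisons. Each gene was drawn independently, so this does not measure how often lists of correlated genes are called without a change. The simulations of unchanged groups drew genes in the same way. A length trend added to 14933 simulated genes gave 5137 calls in knockout-labelled v control and 0 after the correction. Figures and summaries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.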

Results

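Total RNA was sequenced from live CD4+CD8+ double-positive thymocytes sorted from 16 NOD-AI4 mice aged 6 to 7 weeks. NOD-AI4 mice carry the transgenic T cell receptor of AI4, an autoreactive CD8 T cell clone, and the double-positive stage is when thymocytes first have their receptor tested against self peptides. The groups were 6 NOD-AI4 controls (3 males, 3 females), 5 mice labelled as Nfkbid knockouts (4 males, 1 female) and 5 Nfkbid transgenic mice (3 males, 2 females). Nfkbid encodes IκBNS, a nuclear member of the IκB family, and the series title places its overexpression and ablation beside the thymic deletion of AI4 cells. Library totals were 17955743 to 26586220 estimated counts in controls, 21662210 to 35637813 in knockout-labelled and 18546570 to 25836799 in transgenic libraries. Control males had 25052921 to 26586220 and control females 17955743 to 18888169, so sex and depth coincide in the controls. All controls had mouse identifiers with 1 prefix and all other mice another prefix, so a difference from the controls cannot be told apart from a difference between the identifier series, and only the transgenic and knockout-labelled mice can be compared inside 1 series.

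The targeted gene was strongly raised in the transgenic libraries and was not lower in the libraries labelled knockout. Nfkbid (ENSMUSG00000036931, GRCm38 chromosome 7, 30421732 to 30428746) was at 208.1 ± 72.1 CPM (SD, n = 5) in transgenic libraries, 32.7 ± 2.9 CPM (n = 6) in controls and 31.6 ± 4.3 CPM (n = 5) in knockout-labelled libraries. The lowest transgenic library, at 114.7 CPM, lay above the highest other library, at 37.8 CPM. The transgenic level was 6.37-fold that of controls (log2 fold change 2.67, SE 0.15, edgeR adjusted p = 9.8e-08; exact permutation p = 0.00216, the smallest that 462 permutations can give). It was 6.59-fold the knockout-labelled level (log2 fold change 2.61, SE 0.16, edgeR adjusted p = 1.8e-06; exact permutation p = 0.00794, the smallest that 252 permutations can give). Knockout-labelled and control libraries differed by less than the spread between replicates (log2 fold change 0.07, SE 0.15, edgeR adjusted p = 0.78; exact permutation p = 0.608), and the sign of that value turned without knockout replicate 5 (-0.05). The counts therefore do not show the ablation. The labels do not give the allele, and gene-level counts do not resolve which exons the reads cover. These libraries are called knockout-labelled here, and single ones are numbered as knockout replicates after their labels. Transgenic females had 309.6 and 239.0 CPM and transgenic males 114.7 to 194.5 CPM (n = 3); the transgenic effect on Nfkbid was not called different between the sexes (log2 difference -0.54, male over female, SE 0.27, edgeR adjusted p = 0.41). Hcst, which encodes the signalling adaptor DAP10 and lies beside Nfkbid on the opposite strand (chromosome 7, 30417712 to 30419854), had more counts in transgenic libraries (log2 fold change 1.85 against controls, SE 0.14, edgeR adjusted p = 6.0e-07). In each of the 5 transgenic libraries the Hcst excess over the other groups was 7.33% to 8.67% of the Nfkbid excess in CPM, so the counts do not show whether Hcst RNA itself rose or reads of Nfkbid were counted for it.

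**Figure D1:**
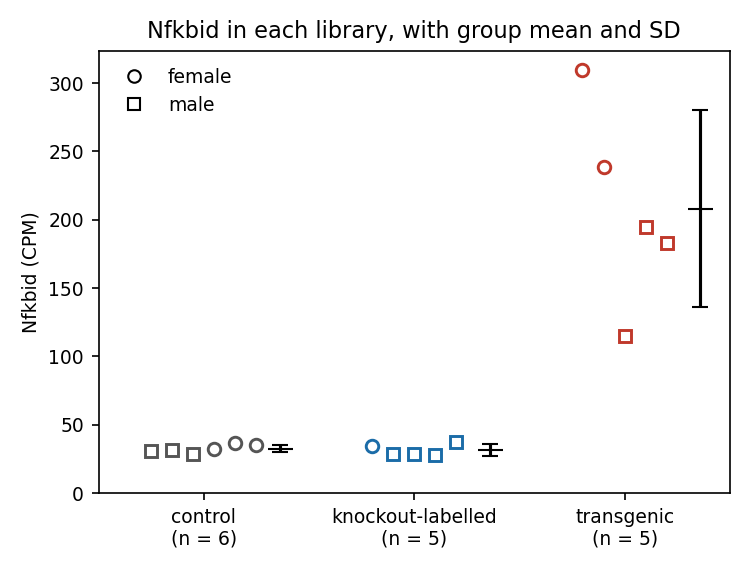
Nfkbid level in each of the 16 libraries, in CPM on TMM-scaled library sizes, by group, with the group mean and SD. All 5 transgenic libraries (114.7 to 309.6 CPM) lie above every control and knockout-labelled library (28.2 to 37.8 CPM).

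In the principal component analysis, the first component (27.5% of the variance) ordered the groups without overlap, with scores of -37.7 to -16.6 in controls, -8 to 12.5 in knockout-labelled and 23.3 to 35.2 in transgenic libraries. The second component (11.6%) parted males from females.

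**Figure D2:**
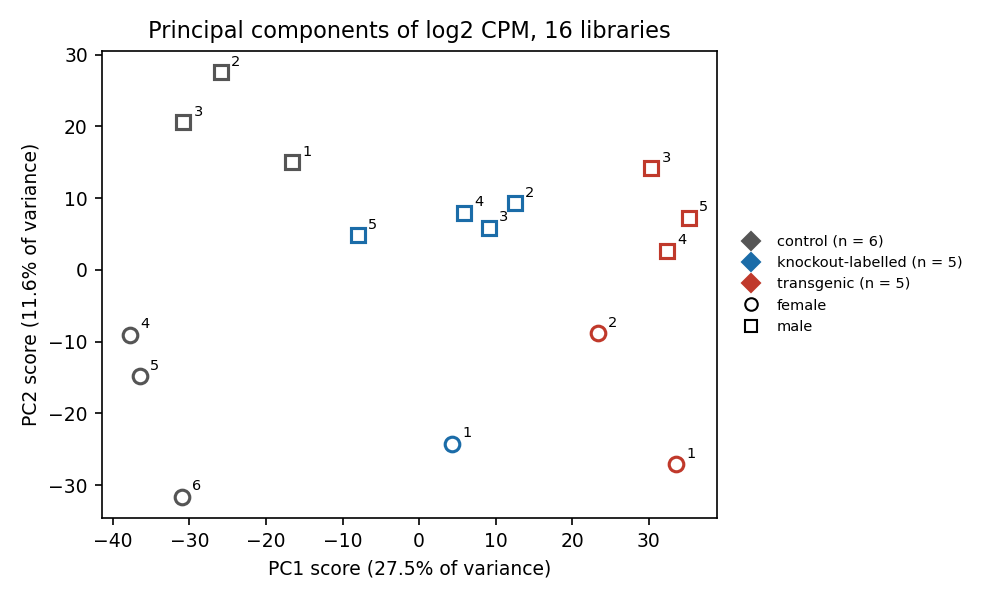
Scores of the 16 libraries on the first and second principal components of log2 CPM, which hold 27.5% and 11.6% of the variance; each point is 1 library, coloured by group and shaped by sex. The first component separates the 3 groups and the second the sexes.

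Against controls, the knockout-labelled libraries had fewer immediate-early transcripts and more transcripts of growth genes. This comparison lies across the identifier series, so it does not isolate the ablation that the labels name. Fos, an AP-1 subunit induced within minutes of stimulation or handling, fell from 81.9 ± 27.7 CPM (n = 6) to 9.86 ± 10.4 CPM (n = 5; log2 fold change -3.21, SE 0.49, edgeR adjusted p = 8.9e-04). Its partner Jun fell by 3.07 (SE 0.52) on the log2 scale, and Ppp1r15a, a stress-response phosphatase regulator, fell by 1.95 (SE 0.23). Myc, a transcription factor that drives growth, rose from 11.8 ± 4.02 to 35.4 ± 14.7 CPM (log2 fold change 1.57, SE 0.26, edgeR adjusted p = 0.00129). Gadd45g, a stress- and receptor-induced growth regulator, fell by 1.45 (SE 0.19) on the log2 scale.

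Of 23 immediate-early and handling-stress genes, 11 fell and 0 rose (11 and 1 adjusted over the list alone; camera adjusted p = 1.0e-05, adjusted p = 0.357 with an estimated correlation). Of 30 proliferation genes, 28 rose and 0 fell, also adjusted over the list alone, among them the mitotic kinase Plk1 (log2 fold change 0.81, SE 0.11) and the replication helicase subunit Mcm2 (0.64, SE 0.10); the 2 not called were Tyms and Ccne2. The proliferation list had a camera adjusted p of 9.3e-16, and adjusted p = 0.418 with an estimated correlation. Of 75 ribosomal protein genes 61 rose, such as Rps16 (0.42, SE 0.06), and the count was also 61 adjusted over the list alone (camera adjusted p = 1.2e-16, adjusted p = 0.462 with an estimated correlation). Of 73 nuclear genes of oxidative phosphorylation 57 rose, or 62 adjusted over the list alone, such as the complex I subunit Ndufa10 (0.37, SE 0.05; camera adjusted p = 1.3e-19, adjusted p = 0.357 with an estimated correlation). Cholesterol synthesis genes rose in 16 of 23 cases (20 adjusted over the list alone; camera adjusted p = 1.9e-08, adjusted p = 0.357 with an estimated correlation). Glycolysis and hypoxia genes rose in 8 of 24 cases (10 adjusted over the list alone), with Gapdh at 0.38 (SE 0.06; camera adjusted p = 0.00782, adjusted p = 0.462 with an estimated correlation). Of 20 unfolded protein and amino acid response genes, 11 rose and 1, Dnajb9, fell (13 and 2 adjusted over the list alone). That list gave a camera adjusted p of 0.00782, and adjusted p = 0.626 with an estimated correlation. The serine pathway enzyme Shmt2 rose by 0.81 (SE 0.14). Beside these rises, the share of counts on Malat1, a nuclear RNA, was 0.42% ± 0.07 in controls, 0.29% ± 0.02 in knockout-labelled and 0.27% ± 0.04 in transgenic libraries, and that on Hrnr was 1.81% ± 0.44, 1.23% ± 0.09 and 1.14% ± 0.12.

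Some genes of the thymocyte programme fell, as did 1493 of all 14933 tested genes, with 26.4% of all genes called in either direction. Of 26 double-positive thymocyte genes, 5 fell, among them Cd4, Bcl6, Ets2 and Themis, and 3 rose (Ptcra, Aqp11 and Mns1), with the same counts adjusted over the list alone; the co-receptor gene Cd4 fell by 0.35 (SE 0.09) on the log2 scale. The call of Ptcra was lost without any 1 of control replicates 1 and 2 and knockout replicates 2, 4 and 5 (adjusted p = 0.0511, 0.0946, 0.0791, 0.0612 and 0.0603). The list had a camera adjusted p of 0.0453, and adjusted p = 0.679 with an estimated correlation. Of 28 TCR signalling components 4 fell (Plcg1, Themis, Ptprc and Carmil2; also 4 adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.626 with an estimated correlation). The calls of Ptprc (adjusted p = 0.0836) and Carmil2 (0.0601) were lost without control replicate 1 and knockout replicates 1 to 3. Their log2 fold changes were then -0.295 and -0.383, against -0.281 and -0.386 with all libraries. After a GC content and length correction Ptprc went from -0.28 to -0.11 (adjusted p = 0.088). In the NF-kB and IkB family, 6 of 18 genes fell and 1, Nfkbib, rose (the same adjusted over the list alone), and the list was not called (camera adjusted p = 0.0898). Tnfaip3, an inhibitor of NF-kB signalling, fell by 0.39 (SE 0.08).

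MHC class II genes, which mark B cells and other antigen-presenting cells, were higher in some knockout-labelled libraries. H2-Ab1 was at 10.5 ± 8.59 CPM (n = 5) against 1.199 ± 1.37 CPM (n = 6) in controls (log2 fold change 3.04, SE 0.81, edgeR adjusted p = 0.0154), and H2-Aa rose by 2.69 (SE 0.74) on the log2 scale. Cd74, the class II invariant chain, was at 27.1, 26.5 and 30.7 CPM in knockout replicates 1 to 3 and at 2.44 and 2.40 CPM in replicates 4 and 5. Control replicate 1 had 9.30 CPM and the other controls at most 2.81. Without knockout replicate 1, adjusted p was 0.0605 for H2-Ab1, 0.0675 for H2-Aa and 0.105 for Cd74. The call of Cd74 was also lost without knockout replicate 2 or 3 (adjusted p = 0.0643 and 0.0781) and without any 1 of control replicates 2 to 6 (0.0666, 0.0619, 0.0594, 0.0582 and 0.0513). Of 14 B cell markers, 4 rose, all class II genes or Cd74, and Cd79b and Ms4a1 fell (5 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.739). The list of NK, innate lymphoid and gamma-delta markers was called higher (camera adjusted p = 0.0286, adjusted p = 0.418 with an estimated correlation), with 2 of 12 members rising, Gzma and Il2rb, also adjusted over the list alone. The call of Il2rb was lost without knockout replicate 1 or 4 (adjusted p = 0.0563 and 0.0607) and in males alone (0.11). That of Gzma, at 365.3 CPM in knockout replicate 4 and 109.9 to 177.7 in the other 4, was lost with only the 2 groups compared (adjusted p = 0.0676), in males alone (0.159), and without the libraries with high class II (0.0872) or high interferon-response transcripts (0.0855). Of 29 type I interferon response genes 0 were called, also adjusted over the list alone, while the list as a whole was called lower (camera adjusted p = 0.0286, adjusted p = 0.829 with an estimated correlation). Without control replicate 2 and transgenic replicates 3 and 5, in which these transcripts were high, the list's direction turned (camera adjusted p = 0.155).

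In all, edgeR called 3942 of 14933 genes at a Benjamini-Hochberg adjusted p under 0.05, 2449 higher and 1493 lower in knockout-labelled libraries, with a median size of 0.33 on the log2 scale; 180 exceeded 2-fold. The split by direction was 2169 higher and 1817 lower with RLE size factors and 2309 and 2025 with DESeq2. Against a fold of 1.2 the count was 414, and without the libraries with high class II transcripts (control replicate 1 and knockout replicates 1 to 3) it was 1438. Among other calls, the setting without those libraries ended those of Jun (log2 fold change -2.65, adjusted p = 0.0726), Cd4 (-0.34, 0.16) and Tnfaip3 (-0.33, 0.0588), with 12 libraries left.

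The transgenic libraries differed from controls in growth and stress genes and in MHC class I presentation, interferon-response and immunoglobulin transcripts. The growth and stress changes were shared with the knockout-labelled libraries. The comparison lies across the identifier series, so it does not isolate overexpression. Psmb9, a subunit of the immunoproteasome that cuts peptides for class I molecules, rose from 28.3 ± 2.82 CPM (n = 6) to 63.2 ± 4.58 CPM (n = 5; log2 fold change 1.16, SE 0.07, edgeR adjusted p = 7.7e-08). Igkc, the kappa light chain constant gene, rose from 0.730 ± 0.973 to 59.9 ± 25.2 CPM (6.21, SE 0.54, edgeR adjusted p = 1.2e-05), and Jchain, which joins secreted antibody units, rose by 4.23 (SE 0.33) on the log2 scale. Irf4, a transcription factor induced by antigen receptor signals, rose by 1.48 (SE 0.20), and Ly75, an endocytic receptor of thymic epithelium and dendritic cells, by 1.25 (SE 0.08). Fos fell to 6.19 ± 1.21 CPM (-3.75, SE 0.50, edgeR adjusted p = 1.5e-04), and the heat-shock gene Hspa1b from 53.7 ± 55.2 to 0.996 ± 1.04 CPM (-5.08, SE 1.26, edgeR adjusted p = 0.00707). The Hspa1b level of controls came mostly from the 3 males (67.5, 119.0 and 116.6 CPM), while the 3 control females were at 5.37, 13.1 and 0.717 CPM and the transgenic libraries at 0.347 to 2.81 CPM.

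All 17 MHC class I presentation genes rose, also adjusted over the list alone (camera adjusted p = 3.7e-13, adjusted p = 0.238 with an estimated correlation). Among 29 type I interferon response genes, 15 rose and 0 fell (20 and 0 adjusted over the list alone), with Gbp2, an interferon-inducible GTPase, at 1.28 (SE 0.16; camera adjusted p = 1.8e-05, adjusted p = 0.538 with an estimated correlation). Ifit1 was at 67.1 CPM in control replicate 2, 145.4 in transgenic replicate 3 and 66.3 in transgenic replicate 5, and at 1.82 to 17.9 CPM in the other 13 libraries. Mature single-positive thymocyte genes rose in 12 of 27 cases and 1, Cd8b1, fell (14 and 1 adjusted over the list alone), with Plac8 at 2.34 (SE 0.43) and Ms4a6b at 0.75 (SE 0.12). That list gave a camera adjusted p of 3.8e-04, and adjusted p = 0.353 with an estimated correlation. Double-positive thymocyte genes fell in 14 of 26 cases and 1, Ptcra, rose, the same adjusted over the list alone (camera adjusted p = 5.9e-05, adjusted p = 0.298 with an estimated correlation). Of 58 TCR alpha variable segments, 14 fell and 0 rose, also adjusted over the list alone, such as Trav7-3 (-1.34, SE 0.27; camera adjusted p = 0.00155, adjusted p = 0.473 with an estimated correlation). Reads of these segments can be shared between near-identical copies, so single segments are uncertain.

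Of the growth lists, 28 of 30 proliferation genes rose (Plk1 0.88, SE 0.11; Ccne1, a G1 cyclin, 0.76, SE 0.09), as did 63 of 75 ribosomal protein genes and 67 of 73 oxidative phosphorylation genes. Adjusted over the list alone the counts were 28, 64 and 67, and the camera adjusted p values were 3.7e-13, 2.3e-19 and 6.2e-21. With an estimated correlation they were adjusted p = 0.298, 0.298 and 0.238. Cholesterol synthesis genes rose in 21 of 23 cases (camera adjusted p = 1.7e-10) and glycolysis and hypoxia genes in 18 of 24 (Pgk1 0.56, SE 0.06; camera adjusted p = 2.4e-05), with the same counts adjusted over the list alone; both had adjusted p = 0.238 with an estimated correlation. Of 20 unfolded protein and amino acid response genes 12 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.538 with an estimated correlation). Immediate-early and handling-stress genes fell in 13 of 23 cases, and 1, Socs3, rose, the same adjusted over the list alone (camera adjusted p = 2.9e-05, adjusted p = 0.24 with an estimated correlation).

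Markers of other cell types were higher beside these groups. Of 14 B cell markers 12 rose, or 13 adjusted over the list alone; Ighm, the mu heavy chain constant gene, was at 352 to 675 CPM in every library and rose by 0.58 (SE 0.06; list camera adjusted p = 1.8e-05, adjusted p = 0.238 with an estimated correlation). Macrophage and monocyte markers rose in 9 of 15 cases and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00305, adjusted p = 0.326 with an estimated correlation). Dendritic cell markers rose in 9 of 12 cases, also adjusted over the list alone, with the integrin gene Itgax going from 0.218 ± 0.237 to 2.38 ± 0.400 CPM (3.36, SE 0.61; list camera adjusted p = 0.00295, adjusted p = 0.353 with an estimated correlation). Of 12 NK, innate lymphoid and gamma-delta markers 5 rose (Tcrg-C2, Trdc, Gzma, Prf1 and Il2rb), also adjusted over the list alone, with the cytotoxic granule protease Gzma at 1.14 (SE 0.23; list camera adjusted p = 0.00961, adjusted p = 0.24 with an estimated correlation). Cd74 was at 19.1 to 38.8 CPM in the 5 transgenic libraries.

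In all, edgeR called 5765 of 14933 genes at a Benjamini-Hochberg adjusted p under 0.05, 3438 higher and 2327 lower in transgenic libraries, and 522 exceeded 2-fold. The split by direction was 2935 higher and 2807 lower with RLE size factors, 3027 and 2883 with DESeq2, and 2755 and 2752 with the stricter filter. Against a fold of 1.2 the count was 1428, and in males alone it was 3160 with 1480 higher and 1680 lower. The males-only fit ended the calls of Itgax (log2 fold change 2.79, adjusted p = 0.0608) and Gzma (1.08, 0.0924), and leaving out control replicate 2 and transgenic replicates 3 and 5 ended that of Hspa1b (-3.53, 0.125).

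**Figure D3:**
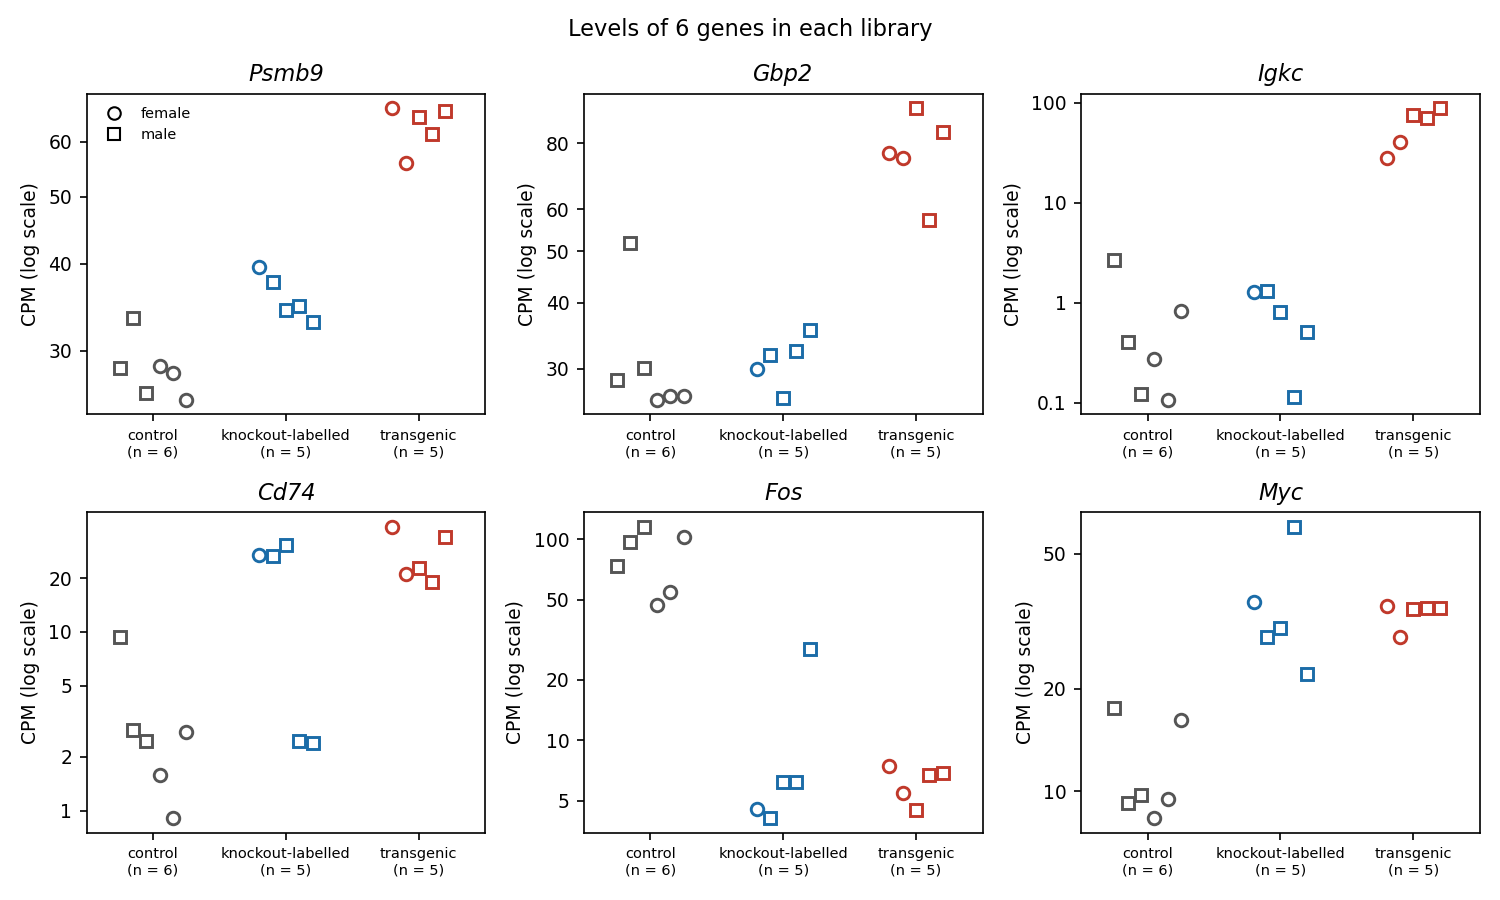
Levels of Psmb9, Gbp2, Igkc, Cd74, Fos and Myc in each library in CPM on a logarithmic axis, by group; circles are females and squares males. Igkc is at 27.6 CPM or more in every transgenic library and at 2.64 CPM or less in every other, while Cd74 is high in knockout replicates 1 to 3 and low in replicates 4 and 5.

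Genes that differed from controls in the knockout-labelled libraries mostly differed in the same direction in the transgenic libraries. Of 3482 genes called in both comparisons, 3479 moved the same way, 2182 higher and 1297 lower, and 3 the opposite way. Fos, Jun, Myc and Plk1 were among those with 1 direction, and the opposite ones were Bcl3, Cd79b and H2-Q4. Bcl3, an atypical IκB protein that partners NF-kB subunits, fell by 1.197 (SE 0.42, edgeR adjusted p = 0.0468) in knockout-labelled and rose by 2.09 (SE 0.35, edgeR adjusted p = 4.0e-04) in transgenic libraries on the log2 scale. Independent lists of these sizes would share 564 higher and 233 lower genes. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.631 and a covariance of 0.141; unchanged groups simulated against the same controls gave a mean correlation of 0.454 (0.425 to 0.481), a covariance of 0.0211, and at most 0 genes called in both. The covariance exceeded the simulated one by 0.12. The simulations drew each gene independently, so their range leaves out correlation between genes. With 3 controls for each comparison, over 20 splits, a median of 1690 genes (1097 to 1944) moved the same way and at most 28 the opposite way, and the median correlation was 0.344. Without the control and knockout-labelled libraries with high class II transcripts the correlation was 0.278. The transgenic libraries, also high in class II transcripts, were kept in that fit.

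**Figure D4:**
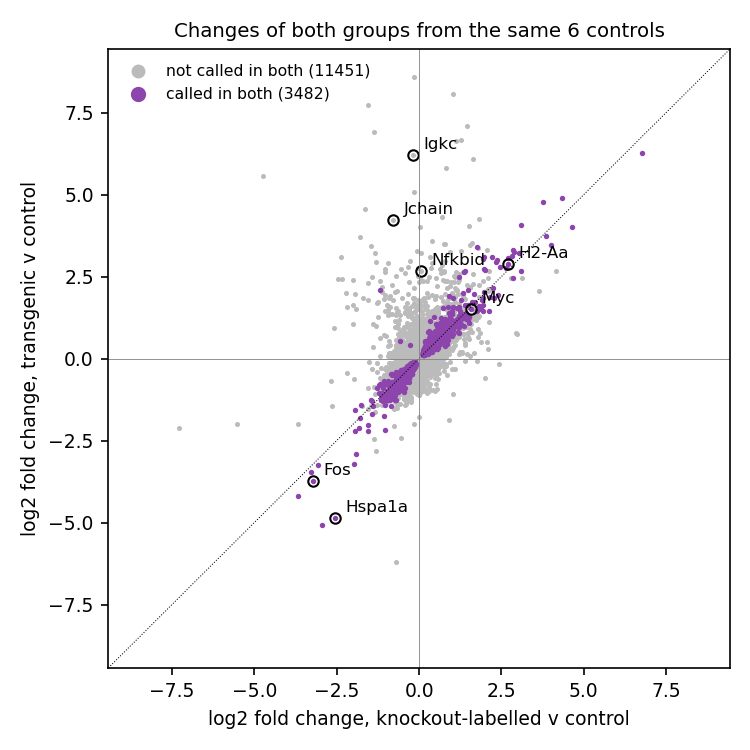
Log2 fold changes against controls of the 14933 tested genes, with knockout-labelled on the horizontal and transgenic on the vertical axis; each point is a gene, and genes called in both comparisons are marked. Of the 3482 marked genes, 3479 lie where both values have the same sign.

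Set directly against the knockout-labelled libraries, inside 1 identifier series, the transgenic libraries had higher MHC class I presentation, interferon-response and immunoglobulin transcripts. Psmb9 was at 63.2 ± 4.58 CPM against 35.9 ± 2.71 CPM (n = 5 each; log2 fold change 0.82, SE 0.08, edgeR adjusted p = 1.3e-05). Igkc was at 59.9 ± 25.2 against 0.805 ± 0.513 CPM (6.39, SE 0.57, edgeR adjusted p = 6.0e-05) and Jchain at 11.3 ± 5.56 against 0.367 ± 0.128 CPM (5.01, SE 0.36, edgeR adjusted p = 2.3e-06). Bcl3 rose from 0.687 ± 0.437 to 7.69 ± 3.67 CPM (3.29, SE 0.42, edgeR adjusted p = 4.8e-04), Irf4 by 1.85 (SE 0.22) and Ly75 by 0.80 (SE 0.09) on the log2 scale. Col1a2, a type I collagen chain, fell from 25.6 ± 8.57 to 10.5 ± 1.36 CPM (-1.29, SE 0.19, edgeR adjusted p = 0.00181), and Foxb1, a forkhead transcription factor, by 0.76 (SE 0.12).

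Of 17 MHC class I presentation genes, 14 rose and Tap2, Pdia3 and Calr were not called (15 rose adjusted over the list alone; camera adjusted p = 4.5e-37, adjusted p = 0.00929 with an estimated correlation). Of 14 B cell markers, 6 rose, among them Cd79b, Ms4a1, Ighm, Igkc and Cd22, or 9 adjusted over the list alone (camera adjusted p = 8.2e-16, adjusted p = 0.0243 with an estimated correlation). These were the only lists of the 3 comparisons whose call held with an estimated correlation. Reads of H2-Q7 (2.35, SE 0.20) and other class I genes can be shared between paralogs and differ between the NOD haplotype and the reference, so single H2 genes are uncertain. Ighg2c, an IgG heavy chain constant gene, had 0 counts over the 5 knockout-labelled libraries and 692 over the 5 transgenic ones (6.53 ± 4.99 CPM), which is at least 279-fold higher against a floor of 3 counts over the group. By symbol, families chosen after their values were seen, 12 of 15 immunoglobulin genes, 10 of 29 H2 genes and 13 of 16 interferon-inducible GTPases rose and 0 fell.

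Of 29 type I interferon response genes 5 rose, among them Oas1a, Ifi27l2a, Zbp1 and Gbp2, or 28 adjusted over the list alone (camera adjusted p = 2.5e-31, adjusted p = 0.14 with an estimated correlation). Without the high-interferon libraries, 12 of the 29 rose. Gbp2 rose by 1.35 (SE 0.17). The call of Oas1a (5.46, SE 1.04) was lost without any 1 of transgenic replicate 3 and knockout replicates 2 to 5 (adjusted p = 0.0607, 0.0535, 0.0673, 0.0725 and 0.0647). Mature single-positive thymocyte genes were called higher (2 of 27 rose, Ms4a4b and Ms4a6b, or 5 adjusted over the list alone; camera adjusted p = 5.0e-09, adjusted p = 0.186 with an estimated correlation). The Ms4a4b call was lost without any 1 of control replicates 1 and 4, transgenic replicates 1, 2, 3 and 5 and knockout replicates 2 to 5 (adjusted p = 0.0552, 0.0525, 0.0573, 0.059, 0.0822, 0.0722, 0.0884, 0.0958, 0.11 and 0.0695). NF-kB target genes were called higher (1 of 20 rose, Ccl5, or 2 adjusted over the list alone; camera adjusted p = 4.1e-04, adjusted p = 0.133 with an estimated correlation), and Ccl5, a T cell chemokine, rose by 2.53 (SE 0.48). Macrophage and monocyte markers (camera adjusted p = 3.4e-11, adjusted p = 0.0586 with an estimated correlation) and dendritic cell markers (9.4e-06, and adjusted p = 0.202 with an estimated correlation) were called higher with 0 of 15 and 0 of 12 members called, or 8 and 5 adjusted over the list alone. Cholesterol synthesis, glycolysis and hypoxia, ribosomal protein and oxidative phosphorylation lists were called higher with 0 members called (2 glycolysis and hypoxia genes adjusted over the list alone, 0 in the others). Their camera adjusted p values were 7.7e-07, 3.0e-05, 3.0e-07 and 9.4e-06, and with an estimated correlation they were adjusted p = 0.193, 0.186, 0.643 and 0.6. Double-positive thymocyte genes were called lower with 0 of 26 members called, also adjusted over the list alone (camera adjusted p = 4.1e-06, adjusted p = 0.202 with an estimated correlation).

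In all, edgeR called 174 of 14933 genes at a Benjamini-Hochberg adjusted p under 0.05, 160 higher and 14 lower in transgenic libraries, and 107 exceeded 2-fold. DESeq2 called 342, males alone gave 106, and a test against a fold of 1.2 gave 99. In males alone the calls of Ccl5 (log2 fold change 2.12, adjusted p = 0.104), Col1a2 (-1.27, 0.105) and Ms4a6b (0.75, 0.0711) were lost. Without control replicate 2 and transgenic replicates 3 and 5 the call of Ighg2c was lost (adjusted p = 0.0662). That setting also ended the calls of Ms4a6b (0.42, 0.0835), Ms4a4b (0.79, 0.123) and Ccl5 (2.73, 0.0637), among others.

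**Figure D5:**
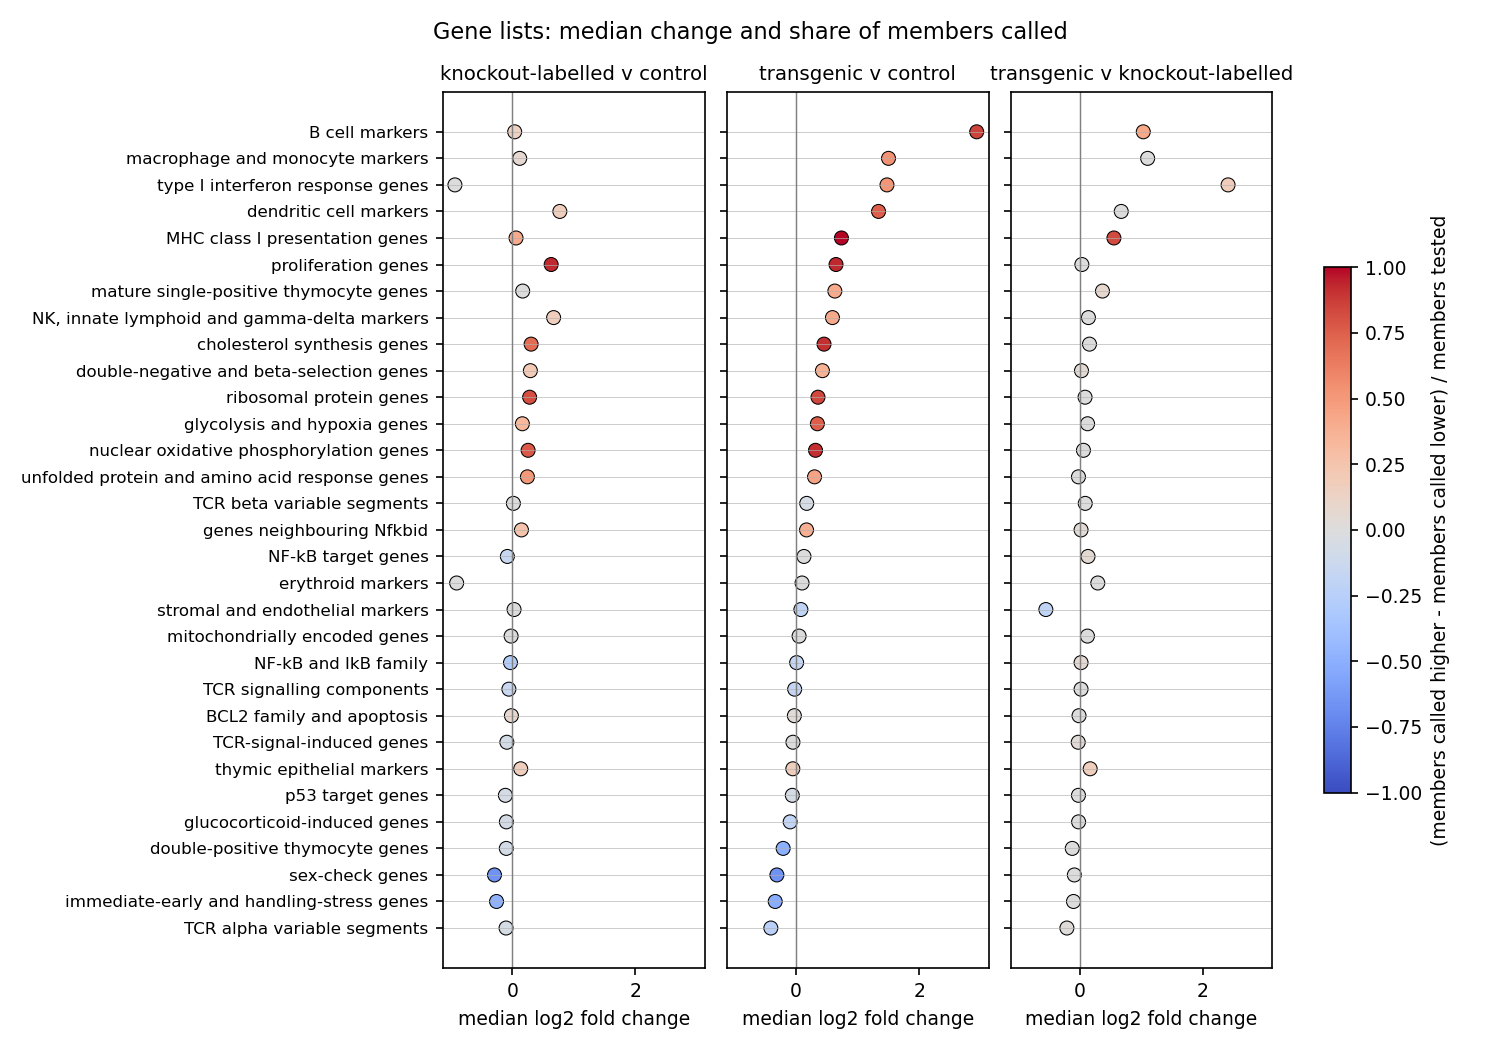
Median log2 fold change of the tested members of each fixed gene list in the 3 group comparisons, with colour for the members called higher minus those called lower, as a share of those tested. The MHC class I presentation and B cell lists are those whose call in transgenic v knockout-labelled libraries held with an estimated correlation.

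The sex of each library followed its label. Xist, the RNA that silences 1 X chromosome, was at 2684 ± 354 CPM in females (n = 6) and 0.691 ± 0.389 CPM in males (n = 10), and the Y-linked helicase gene Ddx3y was at 174.5 ± 40.2 CPM in males and 0 in females. Kdm5d, a Y-linked demethylase, was at 123.9 ± 12.3 CPM in males and 3.46 ± 0.576 CPM in females. Over all groups edgeR called 21 of 14933 genes at a Benjamini-Hochberg adjusted p under 0.05, 9 higher and 12 lower in males; DESeq2 called 110, and without transgenic replicate 2 edgeR called 50. Among males, Ddx3y was lower outside the controls, at 231.0 ± 7.07 CPM in controls (n = 3), 153.9 ± 8.13 in knockout-labelled (n = 4) and 145.5 ± 15.0 in transgenic libraries (n = 3). Of 6 sex-check genes, 4 fell against controls in knockout-labelled and 4 in transgenic libraries (Ddx3y, Eif2s3y, Kdm5d and Uty), also adjusted over the list alone. The list's camera adjusted p was 6.0e-04 and 0.00181, and with an estimated correlation it was adjusted p = 0.357 and 0.238. Without the sex term the knockout-labelled direction turned for Ddx3y (0.08) and for the list (camera adjusted p = 0.998). That fit cannot test the fall among males, since 4 of 5 knockout-labelled but 3 of 6 control mice were male. With the sex term, limma-voom did not call Ddx3y (adjusted p = 0.238 and 0.165).

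The difference between transgenic and control libraries varied with sex for 4 of 14385 genes by edgeR with Benjamini-Hochberg adjustment, each more positive in males. Zfp36l2, an RNA-binding protein that limits mRNA stability, was at 569.4 ± 38.9 CPM in control females and 293.0 ± 20.4 CPM in control males (n = 3 each), against 350.4 ± 32.7 CPM in transgenic females (n = 2) and 364.5 ± 25.4 CPM in transgenic males (n = 3). The log2 difference of its effects was 1.03 (SE 0.12, edgeR adjusted p = 0.0101). The others were AI480526 (1.00, SE 0.11), Vamp2 (0.68, SE 0.10) and Gm38102 (1.43, SE 0.20). The knockout-labelled libraries, outside this fit, had Zfp36l2 at 323.1 CPM in the female and 267.1 to 411.3 CPM in the males. For Zfp36l2, Vamp2 and AI480526 the control females lay above every other library, the knockout-labelled female included. The values therefore do not show an effect particular to the transgene. In the controls sex coincides with depth, and there were 2 transgenic females, and the count went from 0 without transgenic replicate 3 or 4 to 300 without transgenic replicate 1. The calls of Zfp36l2 and AI480526 were lost without transgenic replicate 2, 3 or 4 (adjusted p = 0.0548, 0.0538 and 0.062 for both), and those of Vamp2 (0.0673 to 0.214) and Gm38102 (0.0662 to 0.167) without any 1 of control replicates 1 to 5 and transgenic replicates 2 to 5. DESeq2 called 148, and 1976 genes had an unadjusted edgeR p under 0.05.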

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

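All checks in this part were chosen before the values were seen; no explanation is weighed here. A library was singled out when its gap to the next value took an unusually large share of its group's range (Dixon's criterion). This picked 51 of the 431 groups of values tested, and chance alone picks about 1 in 20; 50 of them are given. Levels are CPM unless stated.

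In control replicate 1, H2-Ab1 was at 3.94 (0.383 to 0.993 in the other controls), H2-Aa at 4.86, Il7r at 3.94, Itgax at 0.689, and the mean log2 CPM of the erythroid markers at 4.02 (1.33 to 1.62). In control replicate 2, interferon-response genes stood above the other controls: Iigp1 was at 13.1 (0.110 to 0.801), Gbp2 at 51.7, Oas1a at 7.92 and Ifit1bl1 at 13.6, with a mean log2 CPM of 5.42 for the type I interferon list (2.36 to 2.92) and 6.68 for the MHC class I presentation list. In control replicate 3, Hcst was low at 3.93 and the cholesterol synthesis mean was high at 4.60 log2 CPM. In control replicate 6, Dusp1 (73.2), Ppp1r15a (105.3), Junb (190.9), Ighm (447.1) and Bak1 (81.7) were high, and Birc2 (75.4), Bcl2l11 (157.3) and Adam12 (43.3) were low. The same library had high mean log2 CPM for TCR signalling components (8.48) and p53 targets (4.61) and low means for double-positive genes (7.55) and TCR alpha variable segments (0.0581, against 0.678 to 0.998).

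Knockout replicate 1, the 1 female of its group, stood apart in sex-linked genes: Ddx3y and Eif2s3y were at 0, Uty at 2.38, Kdm5d at 3.52, Gm27927 at 12.4 and Xist at 2503. Knockout replicate 4 had the largest library, 3.564e+07 counts against 2.166e+07 to 2.434e+07 in the others, with Il7r at 16.8 (2.36 to 3.66), Shmt2 at 100.5, Phgdh at 126.6, Calr at 427.3 and Cox8a at 124.3. Its mean log2 CPM was high for unfolded protein and amino acid response genes (5.88) and low for glucocorticoid-induced genes (5.04). In knockout replicate 5, Fos was at 28.3 (4.09 to 6.18), Jun at 9.05, Tyrobp was low at 0.295, and the TCR beta variable mean was 1.78 log2 CPM.

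In transgenic replicate 1, Fcer1g was at 1.22, Chuk was low at 68.2, and the B cell marker mean was 3.69 log2 CPM (2.59 to 2.77). In transgenic replicate 2, Myc was low at 28.4 (34.3 to 35.2). In transgenic replicate 3, Ms4a4b was at 169.4 (78.4 to 97.0), and Calr (353.0) and Itgax (1.69) were low.

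The difference between transgenic and control libraries varied with sex, by the edgeR test of that variation itself, for Vamp2 (log2 difference 0.676), Zfp36l2 (1.034), AI480526 (0.998) and Gm38102 (1.426). With 1 library left out at a time the number of such genes was 0 without transgenic replicate 3 or 4 and 300 without transgenic replicate 1.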

How the results depend on the processing

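The GC and length correction and the settings without the interferon-high libraries (control 2, transgenic 3 and 5) or the class II-high libraries (control 1, knockout 1 to 3) were chosen after seeing the data; the other settings were planned. The class II-high setting kept the transgenic libraries, in which class II transcripts were also high (Cd74 at 19.1 to 38.8 CPM). It left knockout replicates 4 and 5, at 2.44 and 2.40 CPM, so class II levels stayed unequal between these groups. Where a value moved, the cause was not tested, unless the setting holds fewer samples or asks for a larger fold. In knockout-labelled v control, 3942 genes became 414 against a fold of 1.2, 2289 without the interferon-high and 1438 without the class II-high libraries, and 2863 to 4253 with 1 library left out. In transgenic v control, 5765 became 3160 in males only (1480 higher, 1680 lower), 1428 against a fold of 1.2, and 4687 to 5965 with 1 library left out. In transgenic v knockout-labelled, 174 became 342 with DESeq2, 278 with no filter and 106 in males only. The count was 99 against a fold of 1.2 and 122 to 225 with 1 library left out. Of the 174 genes, 63 were still called in males only, 92 without the interferon-high and 71 without the class II-high libraries. In male v female, 21 became 110 with DESeq2, 13 against a fold of 1.2, 33 after the GC and length correction, 11 without the class II-high libraries, and 17 to 50 with 1 library left out. The interaction's 4 genes became 148 with DESeq2, 2 with limma-voom, 15 with no filter, 2 when not robust, and 0 to 300 with 1 library left out. Lists called with an estimated correlation fell from 14 to 0, from 18 to 0 and from 13 to 2. Without sex 9 were called in knockout-labelled v control, and fry called 7 in transgenic v knockout-labelled. With 1 library left out lists numbered 10 to 14, 18 to 21 and 13 to 18. The 3479 genes called in both comparisons in the same direction became 2018 without the interferon-high and 1267 without the class II-high libraries, a median of 1690 with split controls, and 2573 to 3670 with 1 library left out. The correlation of the 2 effects over all tested genes, 0.631, became 0.278 without the class II-high libraries, 0.344 with split controls, and 0.477 to 0.702 with 1 library left out.

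The Nfkbid value of knockout-labelled v control reversed to -0.048 without sex, -0.009 with only the 2 groups compared and -0.053 without knockout replicate 5 (-0.053 to 0.142 over the libraries left out). With 1 library left out it was 2.54 to 2.807 in transgenic v control and 2.505 to 2.766 in transgenic v knockout-labelled, in males only 2.398 and 2.389, without the interferon-high libraries 2.846 and 2.816, and without the class II-high ones 2.712 and 2.422. In knockout-labelled v control, Wdfy4 reversed to -0.323 and Mpeg1 to -1.215 without the class II-high libraries, and Ddx3y to 0.084 without sex. A fit without sex cannot test Y-linked genes or the sex-check list here, since the share of males differs between these groups. List directions reversed for interferon response in knockout-labelled v control without the interferon-high libraries (adjusted p = 0.155), for sex-check genes without sex (0.998), and for the unfolded protein list in transgenic v knockout-labelled without knockout replicate 4 (0.0333; 0.0333 to 0.988 over the libraries left out). Of the named genes, 14 of 59, 45 of 64 and 11 of 28 were called in every setting of the 3 group comparisons, and 19, 1 and 8 lost their call when some single library was left out. Other scalings moved the median of all genes by less than 0.1 (log2). In simulation 18% of 1.5-fold changes in the interaction were recovered. A fit of male v female with only the groups compared was not run, since both sexes make up all 16 libraries.

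The replicate numbers do not pair the samples: same-numbered knockout-labelled and control libraries deviated together with correlations of -0.026 to 0.253 (over 0.1 in 1 of 5 pairs, highest with their own number in 1), transgenic and control ones with -0.178 to 0.225 (3 and 2 of 5), and transgenic and knockout-labelled ones with -0.149 to 0.189 (1 and 2 of 5). With the replicate block, the 3 comparisons called 4165, 5928 and 165 genes and 13, 18 and 14 lists, male v female called 12 genes, and Nfkbid changed by 0.006, 2.604 and 2.598.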

Other observations

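All tests of explanations below were chosen after the result was seen, except the one on the interferon-high libraries, whose bounds were written before its result was seen; the comparison with other splits of the libraries was also run after the counts were known. Of 25 BCL2 family and apoptosis genes, 7 rose and 5 fell in knockout-labelled against control libraries and 8 rose and 7 fell in transgenic ones (7 and 7, and 9 and 9, adjusted over the list alone); Bak1, a pore-forming death effector, rose by 0.25 (SE 0.05) and Bcl2l11, which encodes BIM, the initiator of thymocyte deletion, fell by 0.40 (SE 0.08) on the log2 scale in transgenic libraries. Of 27 TCR-signal-induced genes, 3 rose and 5 fell in knockout-labelled and 5 rose and 5 fell in transgenic libraries, with Myc and Pdcd1 higher and Gadd45b, Gadd45g, Ikzf2 and Tnfaip3 lower in both (3 and 6, and 4 and 5, adjusted over the list alone). Against knockout-labelled libraries 1, Irf4, rose in transgenic ones. Of 20 NF-kB target genes, 1 rose (Cd83) and 4 fell against controls in knockout-labelled libraries, and 4 rose (Cd83, Ccl5, Tnfrsf18 and Tnfrsf9) and 4 fell in transgenic ones; in both, those that fell were Nfkbia, Tnfaip3, Birc2 and Cflar (1 and 4, and 6 and 4, adjusted over the list alone). Without the class II-high libraries (control replicate 1 and knockout replicates 1 to 3) the knockout-labelled calls of Tnfaip3, Birc2 and Cflar were lost (adjusted p = 0.0588, 0.0603 and 0.0565). Their log2 fold changes were then -0.326, -0.349 and -0.26, against -0.387, -0.308 and -0.243 with all libraries. In the NF-kB and IkB family, 2 of 18 (Nfkbib and Bcl3) rose and 5 fell in transgenic libraries against controls, and 1, Bcl3, rose against knockout-labelled ones (4 and 5, and 1 and 0, adjusted over the list alone). Of 19 double-negative and beta-selection genes, 4 (Kit, Ptcra, Lyl1 and Il7r) were called higher in knockout-labelled libraries, but 0 adjusted over the list alone. In transgenic libraries 8 rose and 1 (Runx2) fell (9 and 2 adjusted over the list alone), and against knockout-labelled ones Spib rose (3 and 1 adjusted over the list alone). The Lyl1 call was lost without control replicate 2 or knockout replicate 1 (adjusted p = 0.0582 and 0.0635), and the Ptcra call without control replicate 1 or 2 or knockout replicate 2, 4 or 5 (0.0511, 0.0946, 0.0791, 0.0612 and 0.0603); the Il7r call was lost without any 1 of 12 libraries, named below with their values. None of these lists was called against controls by camera. For scale, edgeR called 26.4% of all tested genes in knockout-labelled v control and 38.6% in transgenic v control.

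Of 18 p53 target genes 4 rose and 5 fell in each group against controls (7 and 6, and 4 and 5, adjusted over the list alone), and of 16 glucocorticoid-induced genes 1 (Fkbp5) rose in each while 2 fell in knockout-labelled and 4 in transgenic libraries (1 and 4 adjusted over the list alone). MHC class I presentation genes rose in 7 of 17 cases in knockout-labelled libraries (also 7 adjusted over the list alone; camera adjusted p = 0.158), with Psmb9 at 0.34 (SE 0.07); its call was lost in males alone (0.25, adjusted p = 0.0606) and without the class II-high libraries (0.21, 0.242). Of 28 TCR signalling components 1, Cd2, rose and 6 fell in transgenic libraries, the same adjusted over the list alone. Mature single-positive genes had 1 rise (Il7r) and 1 fall (Ccr9) in knockout-labelled libraries, and 0 of each adjusted over the list alone; the Il7r call was lost without any 1 of control replicates 2 to 6 (adjusted p = 0.106, 0.0946, 0.0739, 0.0709 and 0.07), transgenic replicates 1 to 5 (0.0563, 0.058, 0.0605, 0.0599 and 0.0603) and knockout replicates 2 and 4 (0.0512 and 0.158). Genes neighbouring Nfkbid were called higher in knockout-labelled libraries (7 of 24 rose, 1 fell, or 8 and 1 adjusted over the list alone; camera adjusted p = 0.0453, adjusted p = 0.462 with an estimated correlation) and in transgenic ones (10 rose, 1 fell, the same adjusted over the list alone; 0.0309, and adjusted p = 0.326 with an estimated correlation), and against each other 1, Hcst, was higher (2 higher and 1 lower adjusted over the list alone). TCR alpha variable segments were called lower in knockout-labelled libraries (3 of 58 fell, or 0 adjusted over the list alone; camera adjusted p = 0.0453, adjusted p = 0.774 with an estimated correlation) and in transgenic against knockout-labelled ones (0 fell and Trav12-3 rose, the same adjusted over the list alone; 0.00595, and adjusted p = 0.643 with an estimated correlation). TCR beta segments had 1 fall among 19 (0 adjusted over the list alone), Trbv1 in transgenic v control, lost without any 1 of control replicate 4, knockout replicate 1 and transgenic replicates 2, 3 and 4 (adjusted p = 0.0836, 0.0563, 0.0603, 0.0614 and 0.0557). The Trav12-3 call against knockout-labelled libraries was lost without knockout replicate 1 (0.0535). The 13 mitochondrially encoded genes and 7 erythroid markers had 0 calls in the 3 comparisons, and the 1 granulocyte marker tested was not called. Of 6 thymic epithelial markers Ly75 rose in all 3 comparisons, and of 5 stromal and endothelial markers Col1a2 fell in both comparisons of the transgenic libraries; adjusted over the list alone, 1 more of each list was called in transgenic v knockout-labelled libraries. The knockout-labelled rise of Ly75 against controls went from 0.46 to 0.23 without the class II-high libraries and was not called (adjusted p = 0.162), and knockout replicates 4 and 5 (28.78 and 26.6 CPM) lay inside the control range of 21.47 to 29.85 CPM. In knockout-labelled libraries 2 of 15 macrophage markers (Fcer1g and Tyrobp) rose and 1 fell, and 2 of 12 dendritic cell markers (Cst3 and Irf8) rose (2 and 0, and 2, adjusted over the list alone). These calls were lost for Cst3 without knockout replicate 3 (adjusted p = 0.052), for Irf8 without knockout replicate 1 (0.0588), for Fcer1g without control replicate 3, 4 or 5 or knockout replicate 1 or 2 (0.0617, 0.0503, 0.0504, 0.0891 and 0.0769), and for Tyrobp without control replicate 2, 3 or 4 or knockout replicate 1, 2, 3 or 4 (0.0734, 0.0727, 0.0515, 0.1, 0.0684, 0.059 and 0.0546). Cst3 was also not called after the GC content and length correction (0.11, adjusted p = 0.152), and without the class II-high libraries Irf8 went from 0.67 to 0.22 (adjusted p = 0.368). Knockout replicates 4 and 5, at 8.409 and 8.712 CPM of Irf8, lay inside the control range of 6.29 to 10.3 CPM. In transgenic v knockout-labelled libraries 0 genes of the BCL2, TCR signalling, proliferation, glucocorticoid, immediate-early, p53, unfolded protein, NK and sex-check lists were called, also adjusted over the list alone.

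Many genes shifted the same way in the knockout-labelled and the transgenic libraries against the controls. GC content and transcript length do not account for it as the whole cause, since after their smooth was removed 3941 genes were called in knockout-labelled v control, 3138 of them among the original 3942, and 3392 genes against 3479 moved the same way in both comparisons. A response graded by the amount of Nfkbid product would send loss and gain in opposite directions. With separate controls for each comparison at most 28 genes moved in opposite directions and at least 1097 the same way. These counts restate the shared direction and are no separate test of it. Nfkbid counts also show no loss in knockout-labelled libraries (31.6 CPM against 32.7 in controls), so a graded response is not decided here. Also open is a difference in collection or library preparation between the mouse identifier series, which may include the lower Fos transcripts. It cannot be told apart from a group difference, because 0 series hold both controls and another group. Genetic background or housing of the 2 series is likewise untested.

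MHC class I presentation genes were higher in transgenic than in knockout-labelled libraries. The interferon-high libraries alone do not account for it: without them 10 of 17 genes were still called higher, against 14. RNA of antigen-presenting cells would bring class II transcripts at similar levels, but the summed CPM of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 differed by 14.29 (-34.8 to 63.3) and that of the class I list by 1343 (766 to 1921). Reads shared between class I paralogs would leave other members unmoved, yet 10 of the 13 members outside the H2 family were called higher. A response of the thymocytes that comes with the transgene, with or without an interferon signal, is a candidate explanation found and tested on the same 10 mice, and a difference between litters or cages within the series was not tested.

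Immunoglobulin genes were higher in transgenic than in knockout-labelled libraries. Igkc was higher in every transgenic library than in any knockout-labelled one, at 27.6, 40.0, 74.7, 69.4 and 88.0 CPM against at most 1.32. Igha did not part the libraries in this way, since transgenic replicate 2 lay below knockout replicate 1. Transcription of an unrearranged kappa locus would give few variable-gene reads, but kappa variable genes had 0.7049 to 0.8193 of the kappa constant counts in the transgenic libraries. The heavy chain locus was not tested in this way. Heavy chain variable genes summed to 14.4 to 46.8 CPM in transgenic libraries. Ighm was at 562 to 675 CPM there and at 352 to 419 CPM in knockout-labelled libraries. Transcription of unrearranged heavy chain genes therefore stays open for the rise of Ighm. RNA of antibody-secreting cells may be the source and stays open: 3 of the 9 tested secretory markers were higher (Jchain, Mzb1 and Irf4), and Xbp1, Txndc5, Creld2 and Pou2af1, which were at 11.5 to 59.6 CPM in all groups, have a baseline that would hide a small share. The other 2, Prdm1 (0.804 CPM in transgenic and 0.616 in knockout-labelled libraries, adjusted p = 0.848) and Sdc1 (5.75 and 12.6 CPM, adjusted p = 0.357), were not called and add nothing in its favour. Irf4 was highest in transgenic replicates 1 and 2 (13.8 and 12.2 CPM), which had the lowest Igkc and Jchain of the group. Its rise therefore adds nothing in favour of antibody-secreting cells either. The sort on CD4 and CD8 should remove such cells, so free RNA or cells stuck to thymocytes would be needed.

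Other splits of the same libraries into groups of the same sizes were fitted 100 times per comparison, the real split included, with only the groups compared. For knockout-labelled v control 1 split, the real one, gave as many as its 3457 genes and the highest other gave 913. For transgenic v control it was 1 split, with 5568 genes and 548 at most otherwise, and for transgenic v knockout-labelled 1 split, with 143 genes and 128 at most otherwise, in the split that exchanges knockout replicate 1 and transgenic replicate 4. A split that mixes these groups more evenly, with knockout replicates 1 and 5 and transgenic replicates 1 to 3 on 1 side, gave 119. The real split thus ranked first in each of these 3 comparisons, far above the other splits in both comparisons with controls. In transgenic v knockout-labelled libraries it lay close to the splits with 128 and 119 genes. These group splits did not keep the number of each sex in the groups, so they do not exclude chance for the 3 counts. For male v female 2 splits gave at least 21 genes. The other one, which exchanges control replicate 4 and transgenic replicate 2 with transgenic replicate 5 and knockout replicate 5, gave 651. That is several times the real count and points to a structure of the samples whose source was not tested. These splits also did not keep the number of each sex within the groups, so they do not exclude chance for the 21 genes. For the number of lists called, 36, 11 and 36 of the splits gave as many as the real 13, 18 and 13 of these fits or more, with at most 18, 20 and 19 otherwise, so chance cannot be excluded for these numbers.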
